A study of Homo sapiens with 2 samples.

How the data were processed

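Total RNA from parental HL60 cells and from cytarabine-resistant HL60 cells was extracted with TRIzol and made into miRNA libraries with the QIAseq miRNA kit for Illumina sequencing, per the labels' protocols. Each group had 1 library. The submitters' processing notes name bcl2fastq 2.20 and Trimmomatic. The aligner, the read counter, the miRNA catalogue release and the genome build are not given in the sources used here, nor is whether the kit's molecular identifiers were used to collapse PCR copies. If they were not, reads are not independent molecules, and every interval and floor below covers counting error only.

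The values the authors deposited are RPM, reads per 1000000, given with 2 decimals for 2822 rows per library in the same order. The rows cover 2588 mature miRNAs, because 170 miRNAs have more than 1 row (234 rows beyond the first), with nearly the same value in most of them. Among the 31 repeated miRNAs past the filter in the parental library, rows of one miRNA differed by a median of 0.579% and by up to 31.3%. Rows beyond the one used hold 25.5% of the parental and 24.5% of the resistant total, so RPM here are relative to a total in which such reads appear several times. For a repeated miRNA the row with the highest sum of both libraries was used, a choice made after the files were seen. Since RPM are shares, a miRNA that takes more reads lowers all others slightly.

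Whole reads were recovered from the steps between values, each a whole multiple of what 1 read is worth. All values (100%) came out whole within 0.005 RPM in both libraries, with totals over rows of 9210900 reads for parental and 5393754 for resistant cells. With 1 row per miRNA the totals were 6859698 and 4069844. The floor of 3 reads is 0.326 RPM in the parental and 0.556 RPM in the resistant library. A count test such as the quasi-likelihood test of edgeR could not be fitted to these reads, because 1 library per group leaves no residual degrees of freedom, so it calls no genes here.

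The comparison was the ratio of resistant to parental RPM, with no pseudocount, for miRNAs at 10 RPM or more in at least one library. A miRNA was counted when it differed at least 2-fold, which is the threshold the study names. Each ratio has an exact conditional (Clopper-Pearson) 95% interval from the recovered reads. Shares of reads have exact binomial 95% intervals. Lists of miRNAs fixed before the data were examined (27 families, genomic clusters, differentiation and drug response sets, markers of other cell types, and entries thought to collect fragments of other RNAs) were described by their median log2 ratio and its percentile among 10000 random lists drawn from the same abundance deciles. Lists overlap, with 18 miRNAs on more than 1 list, and 4 listed names have no row. Strand balance is log2(5p/3p) for hairpins with both strands at 10 RPM or more in both libraries.

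The rule for named miRNAs, also fixed before the data were examined, took the 10 largest and 10 smallest ratios among miRNAs at 100 RPM or more whose interval lay wholly beyond 2-fold, the 10 most abundant, up to 4 members per list with the largest log2 ratios, and the 5 hairpins with the largest strand difference. Only miR-146a-5p met the first part. The names miR-146a-3p, miR-124-5p, miR-7641, miR-551a, miR-548a-3p and miR-4521 were added after their values were seen, because the count they belong to is small.

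Positions of hairpin genes and what they overlap come from GENCODE release 29 on GRCh38 and not from the deposited values, which carry no coordinates. Hairpin sequences of miRNAs past the filter were searched against annotated ribosomal and small nuclear RNA transcripts, without mitochondrial ribosomal RNA. Exact shared stretches of 18 or more bases were counted. The alternatives tried were median-of-ratios and edgeR TMM scaling, totals without the 10 most abundant miRNAs, leaving out the possible fragment entries, other filters, pseudocounts and thresholds, thinning the parental library to the resistant depth, summed strands, other numbers of top miRNAs, unmatched random lists and a higher strand minimum. Summing or averaging the rows of a miRNA, and a total over 1 row per miRNA, were added after the data were seen.

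The steps were tested on simulated tables of the resistant over parental comparison with 200 of 2588 miRNAs changed. Reads were recovered exactly in 20 of 20 tables. Among simulated miRNAs past the filter, 12 of 12 changed 3-fold, 14 of 14 changed 4-fold and 19 of 19 changed 8-fold were called. Of those changed 1.5-fold 0 of 16 were called, and of the unchanged 0 of 225. Inside their 95% interval lay 93.4% of the true ratios. The simulated libraries varied by counting error alone, so these numbers do not cover variation between cultures or PCR copies. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16, which was used for TMM scaling alone.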

Results

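Small RNA was sequenced from HL60, an established human acute myeloid leukaemia line of promyelocyte-like cells, and from a cytarabine-resistant derivative of it. Cytarabine is a nucleoside analogue that blocks DNA synthesis, and the resistant cells had been selected by growth in rising amounts of the drug. The labels give cytarabine as the treatment of the resistant sample but do not say whether the drug was present when RNA was collected. There was 1 library per group, so no difference below has a replicate check, and no p-value is given. The parental library held 9210900 reads over all miRNA rows and the resistant library 5393754, which makes 1 read worth 0.109 and 0.185 reads per 1000000 (RPM). Brackets after a ratio hold its 95% counting interval, which covers counting error only and says nothing of how far cultures of one kind vary.

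The first question was how alike the miRNA profiles of the parental and the resistant cells were. The haematopoietic miR-142-3p was the most abundant in each, at 207460 RPM in parental and 225152 RPM in resistant cells, or 27.9% and 29.8% of all reads with 1 row per miRNA. The next in mean abundance were miR-16-5p, miR-142-5p, miR-20a-5p, miR-19b-3p, let-7f-5p, miR-223-3p, let-7a-5p, let-7i-5p and miR-26b-5p. Ratios of resistant to parental RPM among these 10 ran from 0.888 for miR-142-5p to 1.13 for miR-223-3p, a miRNA of the granulocyte lineage, which stood at 20855 and 23617 RPM. Together the 10 took 71.4% of reads in each library (exact binomial 95% intervals 71.35% to 71.42% and 71.39% to 71.47%).

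At 10 RPM or more, 274 miRNAs were detected in parental and 278 in resistant cells, and 285 reached that level in at least one. Across these 285 miRNAs, which are not independent replicates, the libraries correlated with a Pearson r of 0.978 on log2(RPM + 1) and a Spearman rho of 0.979. The median log2 ratio was −0.04, with the 5th percentile at −0.38 and the 95th at 0.38, and 273 miRNAs (95.8%) lay within 1.5-fold. Counting intervals excluded a ratio of 1 for 65 miRNAs with the higher value in resistant cells and 75 with the lower. This split depends on the scaling, because TMM scaling raised all log2 ratios by 0.06, which moves some of these intervals across a ratio of 1. Whether these differences exceed the variation between cultures cannot be known from 1 library each.

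The main comparison asked which miRNAs differed at least 2-fold between resistant and parental cells, the size the study screened for. Of the 285, 6 were at least 2-fold higher in resistant cells, 2 were at least 2-fold lower (25% of the 8) and 277 lay in between. Both strands of miR-146a, which is induced by NF-κB and targets the signalling proteins TRAF6 and IRAK1, were among the higher ones. The dominant strand, miR-146a-5p, stood at 84.0 RPM in parental and 7595 RPM in resistant cells, a ratio of 90.4 (84.2 to 97.2; 774 and 40964 reads). It moved from rank 138 to rank 17 by abundance, from 0.0113% to 1.01% of reads. Its partner strand miR-146a-3p stood at 0.54 and 46.4 RPM, a ratio of 85.8 (36.1 to 265; 5 and 250 reads). The near-identical miR-146b-5p, from another gene, stood at 154 and 144 RPM, a ratio of 0.933 (0.853 to 1.02). In GENCODE release 29 on GRCh38, MIR146A lies on chromosome 5 at 160485352 to 160485450, plus strand, in exonic sequence of the long non-coding RNA gene MIR3142HG.

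Both strands of miR-124, a miRNA best known from neurons, were also higher in resistant cells, at low levels. The values of miR-124-3p were 4.02 and 25.4 RPM, a ratio of 6.32 (4.37 to 9.36; 37 and 137 reads), and those of miR-124-5p were 6.19 and 28.6 RPM, a ratio of 4.61 (3.38 to 6.37). Its hairpin has 3 genes, MIR124-1 on chromosome 8 at 9903388 to 9903472 (exonic in LINC00599), MIR124-2 on chromosome 8 at 64379149 to 64379257 (intronic in MIR124-2HG) and MIR124-3 on chromosome 20 at 63178500 to 63178586 (antisense to an intron of AL096828.1), and the mature sequences do not tell which gave the reads. The other higher miRNAs were miR-7641 and miR-1290, each with a limit on its value. For miR-7641 the values were 0.11 and 38.0 RPM from 1 and 205 reads, a ratio of 346 with an interval from 62.1 to 13894, and 50 of the 53 bases of the hairpin MIR7641-2 also occur in a row in the 5S ribosomal RNA gene RNA5S1. For miR-1290, which lies in an intron of ALDH4A1 on chromosome 1 at 18897071 to 18897148, they were 41.5 and 84.0 RPM, and its ratio of 2.03 (1.76 to 2.33) had an interval reaching below 2.

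The lower miRNAs were miR-551a and miR-548a-3p. MIR551A lies in an intron of MEGF6 on chromosome 1 at 3560695 to 3560790, minus strand. The level of miR-551a was 66.9 RPM in parental and 19.3 RPM in resistant cells, 3.47-fold lower (2.81 to 4.31; 616 and 104 reads). The primate-specific miR-548a-3p stood at 10.8 and 3.52 RPM, a ratio of 0.327 (0.189 to 0.539; 99 and 19 reads). It has 3 hairpin genes, MIR548A1 and MIR548A2 on chromosome 6 (18571784 to 18571880, intronic in MIR548A1HG, and 135239160 to 135239256) and MIR548A3 on chromosome 8 (104484369 to 104484465), and many close relatives that can share reads, so its value is uncertain. Just short of the threshold was miR-4521 (chromosome 17, 8186945 to 8187004, in no other gene), at 257 and 137 RPM, a ratio of 0.532 (0.490 to 0.579). The counting interval lay wholly beyond 2-fold for 5 of the 6 higher and 1 of the 2 lower miRNAs, the exceptions being miR-1290 and miR-548a-3p. Of the 8, miR-146a-5p alone reached 100 RPM in its higher library, and the counts depend on the 10 RPM filter, with 29 higher and 31 lower at a filter of 1 RPM.

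**Figure D1:**
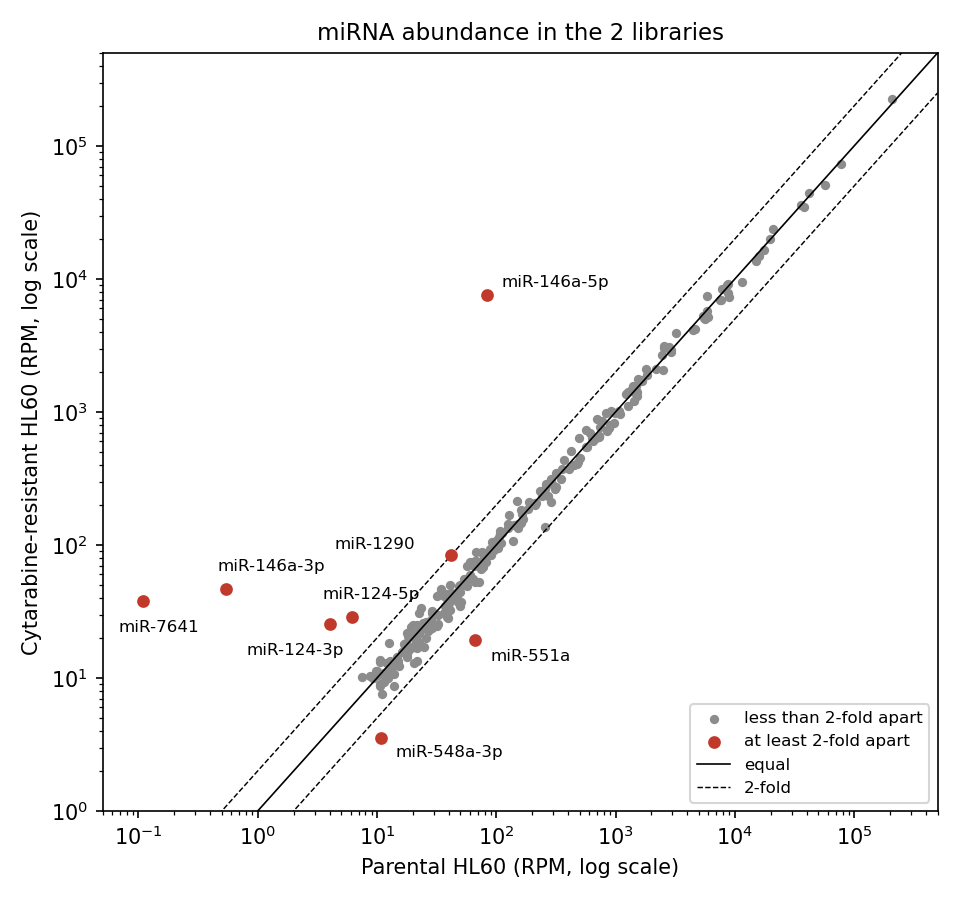
Each point is 1 of the 285 miRNAs at 10 RPM or more in at least one library, with its RPM in parental HL60 on the horizontal and in cytarabine-resistant HL60 on the vertical log axis; the solid line marks equal values and the dashed lines 2-fold. The 8 named miRNAs in red lie 2-fold or more from equality, and miR-146a-5p (84.0 and 7595 RPM) is the only one of them above 100 RPM.

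The next comparison asked whether miRNA families, clusters and cell type markers moved as groups. Of 27 lists, 19 had 3 or more members past the filter, and the median log2 ratio of each was ranked among 10000 random lists of the same size and abundance. The medians of 3 lists lay above the central 95% of random lists and none (0) lay below it. If members varied independently, 0.95 lists would be expected outside. Many lists hold both strands of a hairpin or neighbouring hairpins, which can vary together. More than 0.95 could therefore lie outside by chance, and how many is not known. The miR-181 family acts in lymphoid and myeloid differentiation. All 5 of its members past the filter had ratios above 1, with a median log2 ratio of 0.27 (percentile 99.1). Among them miR-181a-5p stood at 571 and 736 RPM, a ratio of 1.29 (1.24 to 1.34), and miR-181b-5p at 366 and 437 RPM, a ratio of 1.19. All 4 members of the miR-221 and miR-222 cluster, whose targets include the receptor KIT, had ratios above 1, with a median of 0.26 (percentile 98.7). The leading member miR-221-3p stood at 3191 and 3958 RPM, a ratio of 1.24 (1.22 to 1.26). No member of either list past the filter differed 2-fold.

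The list of miRNAs linked to drug response in acute myeloid leukaemia had 7 members past the filter, 4 with ratios above 1 and 3 below, none (0) beyond 2-fold. Its median was 0.18 (percentile 98.5), but this turned to −0.11 (percentile 13.8) with a filter of 1 RPM, and 2 of its members are also on the miR-181 list. Its largest ratio was that of miR-21-5p, widely abundant in tumours, at 5819 and 7503 RPM (1.29, 1.27 to 1.31), and its smallest that of miR-125b-5p, at 875 and 754 RPM (0.862, 0.830 to 0.896). The myeloid differentiation list had 12 members past the filter, of which miR-146a-5p was at least 2-fold higher and 11 lay in between, with a median of 0.01 (percentile 82.0). Among those 11, miR-126-5p stood at 21.8 and 13.4 RPM, a ratio of 0.612 (0.461 to 0.804), miR-126-3p at 49.7 and 34.5 RPM, and miR-21-3p at 128 and 168 RPM.

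The growth-promoting MIR17HG cluster, which encodes miR-17 to miR-92a, had 11 members past the filter with a median of −0.08 (percentile 33.6). Within the cluster, miR-17-5p stood at 5928 and 5139 RPM. Its paralogous clusters at MCM7 (miR-106b, miR-93 and miR-25) and on the X chromosome (miR-106a to miR-363) had medians of −0.01 (percentile 52.9) and 0.09 (81.7). The let-7 family, 9 members that restrain growth, had a median of 0.00 (percentile 71.6), whereas all 8 measured let-7 passenger strands had ratios below 1, with a median of −0.20 (percentile 2.58). In the miR-30 family 7 of 8 ratios were below 1, with a median of −0.18 (percentile 2.82), and miR-30a-5p stood at 20.4 RPM in parental cells with a ratio of 0.636 (0.476 to 0.841). With TMM scaling these passenger strands (percentile 2.17) and the miR-30 family (2.45) came to lie below the random range. The cluster of miR-424, miR-503, miR-450 and miR-542 had a median of −0.18 (percentile 4.76), and that of miR-23, miR-27 and miR-24 one of 0.15 (95.8), with miR-23a-3p at 2543 and 3110 RPM. None of these 8 lists had a member past the filter that differed 2-fold.

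The remaining family lists lay well inside the random range, and none of their members past the filter differed 2-fold. Medians were −0.06 for miR-15 and miR-16 relatives (percentile 23.9), −0.09 for miR-29 (33.6), 0.09 for the miR-99, miR-100 and miR-125 clusters (85.3), −0.06 for miRNAs of the HOX clusters (25.1) and −0.03 for miR-183, miR-96 and miR-182 (54.9). The medians of let-7, of the MCM7 cluster and of the miR-183 list were so close to 0 that they changed sign with the scaling. Of the p53-induced miRNAs, no miR-34 member reached 10 RPM (highest 4.56 and 2.22 RPM), while miR-192-5p stood at 66.0 and 52.3 RPM and miR-194-5p at 46.5 and 41.3 RPM.

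Of the markers of other cell types, only the endothelial and stromal list had 3 or more members past the filter. These 7 endothelial and stromal markers past the filter had a median of −0.08 (percentile 25.8). Of the lymphoid markers, miR-150-5p stood at 12.3 and 10.0 RPM, a ratio of 0.816 (0.579 to 1.14), and miR-155-5p had 14 reads in parental and 0 in resistant cells (floor of 3 reads 0.556 RPM), a ratio whose upper counting limit of 0.515 does not exclude less than a 2-fold difference. Epithelial miR-141-3p stood at 41.8 and 43.6 RPM and miR-200c-3p at 12.1 RPM in parental cells with a ratio of 1.08. No erythroid marker exceeded 0.87 RPM, no miRNA of the imprinted cluster at 14q32 exceeded 0.98 RPM, and none of the primate cluster at 19q13 with miR-371 to miR-373 exceeded 0.33 RPM. On the liver, muscle and neuron list, miR-124-3p was higher as given above, while miR-128-3p stood at 1499 and 1402 RPM (0.935, 0.909 to 0.962) and neuronal miR-9-5p at 2.39 and 2.78 RPM. Of the entries thought to collect fragments of other RNAs, 8 passed the filter, with a median of 0.14 (percentile 97.4). Among them miR-1290 was above 2-fold and miR-1246 stood at 150 and 212 RPM.

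**Figure D2:**
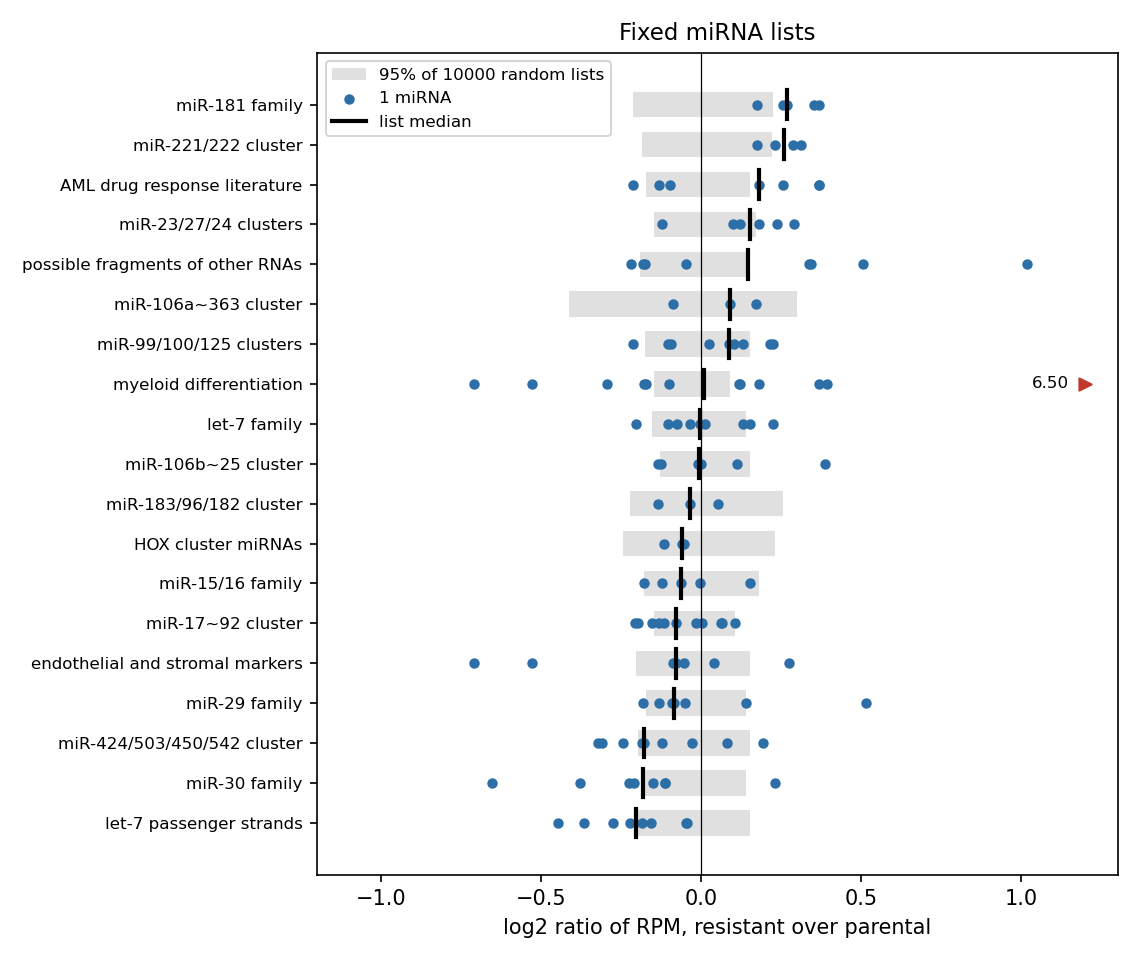
Black bars mark the median log2 ratio (resistant over parental) of each of the 19 lists with 3 or more members past the filter. Blue points are those members, and the grey bar is the central 95% of 10000 random lists matched on abundance. The red arrow stands for miR-146a-5p, whose log2 ratio of 6.50 lies beyond the axis. The medians of the miR-181 family (0.27), the miR-221 and miR-222 cluster (0.26) and the drug response list (0.18) lie beyond their grey bars.

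A last comparison asked whether the balance between the strands of a hairpin differed, a ratio within each library that no scaling between libraries can move. Of 71 hairpins with both strands at 10 RPM or more in both libraries, 0 had log2(5p/3p) differ by 1 or more. The 5 largest differences, resistant minus parental, were −0.52 for miR-93 (7.78 to 7.26), 0.49 for miR-374b, −0.43 for miR-301b, 0.41 for let-7d and 0.41 for miR-330. These differences have no counting interval. Some rest on few reads, with 129 and 58 for miR-301b-5p and 106 and 59 for miR-330-3p. With a strand below 10 RPM in parental cells, miR-146a had log2(5p/3p) of 7.28 in parental and 7.36 in resistant cells, and miR-124 had 0.62 and 0.17.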

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

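Summing or averaging rows and the total over 1 row per miRNA were chosen after the data were seen; the other alternatives were planned. All 8 miRNAs that differed 2-fold kept that call under the 3 other scalings, a pseudocount of 1 RPM and thinning of the parental library, and no log2 ratio of these 8 changed sign under any alternative run. Of 931 log2 ratios of named miRNAs under the alternatives, 860 moved by less than their counting interval and 71 by more. A change of filter cannot move a ratio, and summing or averaging rows cannot move that of a miRNA with 1 row. Part of the 860 was therefore fixed in advance, so their share does not measure how stable the ratios are. The scalings raised all log2 ratios by 0.04 (median of ratios), 0.06 (TMM) and 0.00 (totals without the top 10). Without a pseudocount, the log2 ratio of miR-146a-5p ranged from 6.48 to 6.55 and that of miR-7641 from 7.68 to 8.49. The calls of miR-1290 and miR-548a-3p ended with a pseudocount of 10 RPM and with intervals wholly beyond 2-fold, and that of miR-1290 also with the total over 1 row per miRNA (log2 ratio 1.00, just under the threshold). Leaving out the possible fragment entries removed miR-1290 itself, which left 5 higher and 2 lower. The 5 still held miR-7641, which is not on that list but may also reflect fragments, as described below. A filter of 100 RPM kept miR-146a-5p alone, and a threshold of 4-fold lost miR-1290, miR-548a-3p and miR-551a.

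The counts followed the filter by construction. With no filter, 140 miRNAs were higher and 280 lower (66.7% lower), 967 and 823 were detected, and Spearman rho was 0.899. A filter of 1 RPM gave 29 higher and 31 lower, with 498 and 501 detected. A filter of 100 RPM gave 1 higher and 0 lower (0%), with 127 and 128 detected and a rho of 0.959. The number lower was 1 with a pseudocount of 10 RPM, 6 at 1.5-fold, 0 at 4-fold (0%), 1 for intervals wholly beyond 2-fold and 4 with rows summed, where miR-3179 and miR-6511a-3p joined. The share of reads in the top miRNAs was 56.6% and 56.9% for 5, 83.6% and 82.9% for 20, 71.4% and 71.5% without possible fragment entries, 73.9% and 73.7% with rows summed and 71.4% and 71.5% with rows averaged.

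The drug response list reversed, to a median of −0.13 (percentile 9.33) with no filter and −0.11 (percentile 13.8) at 1 RPM, where more of its members entered. Across alternatives 203 list medians stayed within their interval and 17 moved further, and medians near 0 (let-7, the MCM7 cluster, miR-183 and myeloid differentiation) changed sign under some. With TMM scaling the let-7 passenger strands (percentile 2.17) and miR-30 (2.45) came to lie below the random 95% range. Depth limits miRNAs under 10 RPM most, where 0 of 757 had an interval beyond 2-fold. No paired analysis was possible because each group has 1 library, and no library could be left out.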

Other observations

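The grouping by genomic cluster and all tests in this part were chosen after the results were seen. Hairpin genes within 10000 bases of each other formed 23 clusters with 3 or more miRNAs past the filter, counting only miRNAs with 1 hairpin gene. Of these clusters, 3 had medians outside the central 95% of random lists, where 1.15 would be expected if members varied independently. Neighbouring hairpins and strands of 1 hairpin can vary together, so more than 1.15 could lie outside by chance. The cluster from MIR188 to MIR660 (X chromosome, 50003148 to 50013337, GRCh38) includes miR-362, miR-500a and miR-532. All 8 of its miRNAs past the filter had ratios above 1 in resistant cells, with a median log2 ratio of 0.25 (percentile 99.6). In this cluster miR-532-3p stood at 22.7 and 31.0 RPM and miR-660-5p at 608 and 690 RPM. The cluster of MIR221 and MIR222 (45746157 to 45747124), on the same chromosome, had 4 of 4 ratios above 1 and a median of 0.26 (percentile 99.2). These are the same 4 miRNAs as in the list described above. The other X chromosome clusters went both ways, and among them MIR374A and MIR545 was the third outside the random range, on its lower side. Medians were 0.14 (percentile 85.7) for MIR374B and MIR421, 0.09 (81.5) for MIR106A to MIR20B, −0.05 (39.4) for MIR98 and MIRLET7F2, −0.18 (3.81) for MIR424 to MIR542 and −0.23 (2.44) for MIR374A and MIR545. Over the 44 miRNAs past the filter whose only hairpin gene lies on the X chromosome the median was 0.10. None of these miRNAs differed 2-fold.

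The ratio of about 90 for miR-146a-5p was the pattern that stood out most. Reads of miR-146b would need that miRNA to be higher too, and the ratio of miR-146b-5p was 0.933 (0.853 to 1.02). Over-amplification of a single small RNA would leave the other strand, a different sequence, where it was, but the ratio of miR-146a-3p was 85.8 (36.1 to 265). RNA from lymphoid cells rich in miR-150-5p would raise that miRNA. Its ratio was 0.816 (0.579 to 1.14), a gain of −2.26 RPM where miR-146a-5p gained 7511 RPM. These values argue against each as the cause. RNA of other cells, among them lymphoid cells low in miR-150-5p, remains open. So do the resistant state itself, drug present at harvest, drift of a clone during selection and variation between cultures. None of these was tested, with 1 library per group and no measurement of the primary transcript used here.

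The miR-124 strands had ratios of 6.32 (miR-124-3p) and 4.61 (miR-124-5p). For RNA from neural cells the marker looked at was miR-9-5p, which gained 0.39 RPM (−1.05 to 3.22) where miR-124-3p gained 21.4 RPM. This decides nothing, because miR-9-5p lay under 10 RPM in both libraries and its proportion to miR-124 in neural RNA was not measured here. Neural RNA, the resistant state itself, variation between cultures and, at this low level, carry-over from another library of the same run remain open.

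The higher value of miR-7641, 1 read against 205, may reflect fragments of 5S ribosomal RNA. A stretch of 50 bases of the hairpin MIR7641-2 (chromosome 14, 75604209 to 75604261, within an intron of FLVCR2 and over a 5S pseudogene) occurs in RNA5S1. The search covered 237 hairpins, all of miRNAs past the filter, and left out mitochondrial ribosomal RNA. The only 2 hairpins that shared 18 or more bases with the ribosomal RNA searched or its pseudogenes were those of miR-7641. The median longest match was 10. With small nuclear RNA, 5 hairpins shared 18 or more bases, among them MIR1246 with 19. Among the 8 listed fragment entries past the filter, the largest ratio was 2.03 (1.76 to 2.33), for miR-1290. That is far below the lower limit of 62.1 for miR-7641, so those 8 entries did not rise to a like extent. This cannot decide whether fragments of structural RNAs rose in general, because no hairpin of those 8 shared such a stretch with ribosomal RNA. Hairpins of the listed entries below the filter were not searched. Which molecule the 205 reads came from cannot be read from a table of values without sequences.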
